A study of Homo sapiens with 6 samples.

How the data were processed

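RNA sequencing was analysed from 6 libraries of SUM159, a triple-negative human breast cancer line. The labels separate the cells by their level of ITGB4, the integrin beta-4 subunit. Of the libraries, 1 came from cultured ITGB4-high cells, 2 from cultured ITGB4-low cells (clones 1 and 3), 2 from ITGB4-low cells recovered from mouse lungs in which LM2 cells were also present (clones 1 and 3), and 1 from ITGB4-low clone 1 recovered from lungs of mice given bleomycin through the trachea. LM2 is a lung-metastatic derivative of the breast cancer line MDA-MB-231, and bleomycin is a drug that injures and inflames the lung. Per the series' design text, lungs were dissociated, the suspension was cultured overnight, and tdTomato-positive cells were sorted on the following day. The ITGB4-high and control cells were grown in dishes. The steps through the lung therefore go with the trigger, and lungs that held ITGB4-low cells without a trigger were not analysed here.

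Messenger RNA was captured with oligo-dT and made into strand-marked libraries with the KAPA mRNA HyperPrep kit, per the labels' protocols. Reads were aligned with STAR 2.7.1a to hg38, per the submitters' processing notes. The deposited values are raw whole-number counts of reads per gene, 1 column per library. The counter, its annotation release and its strand setting are not given in the sources used here. Counts of overlapping genes on opposite strands, and of close paralogs such as keratins, are therefore uncertain to the extent that shared reads were split or dropped. The table had 58336 genes, of which 58216 identifiers matched GENCODE release 29 and 120 did not. Gene coordinates are from that annotation (GRCh38, the same assembly as hg38).

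Total counts ran from 13607953 to 22222121 per library, and mitochondrially encoded transcripts took 5.35% to 7.08% of them. A floor of 3 counts, the upper limit that a count of 0 allows, corresponds to 0.135 to 0.22 CPM (counts scaled to a library total of 1e6). Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Normalised levels in CPM were computed from the counts with TMM factors.

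The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM factors, robust empirical Bayes and the filterByExpr filter at a minimum count of 10, which left 15673 genes. P-values were adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05 and no fold minimum. If no gene changed, a share of about 0.05 of the genes would still have an unadjusted p under 0.05. All 6 libraries entered each fit so that groups of 1 library took their spread from the groups of 2. A fit with 4 groups (2 residual degrees of freedom, common biological coefficient of variation 0.244) served LM2 lung cells against control, bleomycin lung cells against control, ITGB4-high against control, and bleomycin against LM2. A fit with 3 classes (3 residual degrees of freedom, 0.243) served all 3 lung-recovered libraries against control and against ITGB4-high. In the fit with 4 groups, replicates are 1 library per clone. The lung class of the fit with 3 classes holds clone 1 under both triggers and clone 3 under LM2, so its libraries are not all separate clones. P-values measure the spread between these libraries. Some genes that passed are not reported here. Genes were named by a rule: adjusted p under 0.05, a mean log2 CPM of 2 or more, the same direction in every library pair, and the largest fitted log2 change, up to 10 higher and 10 lower for ITGB4-high or all lung cells against control, 6 and 6 for the other comparisons with a control or with ITGB4-high, and 5 and 5 for bleomycin against LM2. Names that are only locus identifiers, antisense genes and pseudogenes were left out of the rule. To these were added 25 core genes of the epithelial and mesenchymal states, the EGF family, inflammation and cycling, and up to 4 called members of each list described. Of the core genes, CDH1 and EPCAM did not pass the filter.

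Gene lists were tested with camera in limma 3.58.1, at a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2. Of 31 lists, 29 had at least 5 tested members. The lymphocyte list had 0 tested members and the erythroid list 1. Adjustment was over the 29 lists. Camera was repeated with the correlation estimated from the data, and fry, which tests whether a list's genes move on balance in one direction, was run beside it. Changes adjusted over the list alone were counted as well. The gene lists, the tests, the naming rule and the alternatives were fixed before the data were examined, except where the text states otherwise.

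Clone numbers pair libraries because same-numbered libraries come from the same clone, per their titles. The treatment description names clone 1 alone, so clone 3 for the other LM2 library, and with it the ratios and block that use it, rests on a title. The correlation of the clone deviations from their group means was 0.00847 over 10746 genes with a mean log2 CPM of 2 or more. The clone difference in controls thus did not recur in the LM2 pair, so pairing by clone rests on the titles and not on the counts. Correlations of log2 ratios across genes used pairs of libraries that shared no library. Bleomycin and LM2 ratios over the same clone 1 control were set against 20 simulations with no effect. Chromosome medians of log2 ratios used 9640 genes with a mean log2 CPM of 3 or more and 10000 random gene sets of the same size and level. The chromosome medians were added after the data were seen.

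The procedure was tested on simulated counts with 200 changed genes. At the estimated spread it recovered 14.9%, 86.6% and 98.5% of 2-fold, 4-fold and 16-fold changes for LM2 lung cells against control (15151 genes fitted), 7.46%, 67.2% and 97% for bleomycin (15180 genes), 2.99%, 68.7% and 98.5% for ITGB4-high (15195 genes), and 47.8%, 94% and 100% for all lung cells against control (15191 genes). False calls numbered 24, 34, 25 and 16. Even with all 200 changed genes called, each count would be a larger share of the calls than the adjusted threshold aims at. The genes called in the data may therefore include more false calls than their adjusted p-values imply. In the data the smallest change called was 18.05-fold for LM2, 12.1-fold for bleomycin, 9.885-fold for ITGB4-high and 2.107-fold for all lung cells. The biological coefficient of variation was 0.31 in the LM2 pair and 0.078 in the control pair. The recovered shares may therefore be too high for LM2, bleomycin and ITGB4-high against control. Genes not called there were not shown to be unchanged. Simulated with all lung cells against control, camera recovered 10 of 10 shifted lists and called 0 of 400 unshifted lists. Genes were simulated independently and the unshifted lists were random, so this does not cover lists whose genes move together. In the data, for all lung cells against control, the estimated correlation was 0.623 for NF-kB and cytokine genes and 0.83 for G2/M genes. For p53 targets it was 0.0164, close to the preset 0.01.

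Alternatives were DESeq2 (1.42.0), limma-voom, size factors by the median-ratio (RLE) method, no filter or a filter of 1 CPM in 2 libraries, no robust empirical Bayes, a fold minimum of 2, the clone as a replicate block, and leaving out each library in turn. Added after the data were seen were a fit without the genes of chromosomes 4, 11 and 13, and limma-voom with separate sample weights for lung and dish libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.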

Results

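Poly(A) RNA was sequenced from SUM159 cells that differ in ITGB4, the beta subunit of the laminin-binding integrin that anchors epithelial cells at hemidesmosomes. The groups were cultured ITGB4-high cells (n = 1), cultured ITGB4-low control cells (n = 2, clones 1 and 3), ITGB4-low cells from lungs shared with LM2 cells (n = 2, clones 1 and 3) and ITGB4-low cells from bleomycin-treated lungs (n = 1, clone 1). Total counts were 13607953 for ITGB4-high, 14013264 and 22222121 for control clones 1 and 3, 13647997 and 15298001 for LM2 clones 1 and 3, and 15446892 for bleomycin clone 1. The control pair was close, with a biological coefficient of variation of 0.078 over 10575 genes. The LM2 pair differed more, at 0.31 over 10408 genes. Both pairs differed by more than sampling noise, with a chi-square per degree of freedom of 11.1 and 105, so neither was 1 library counted again. Libraries were treated as separate replicates because the labels name separate samples.

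ITGB4-high cells were first compared with ITGB4-low controls, which checks the labels and asks what separates the 2 states in culture. ITGB4 (ENSG00000132470, chromosome 17, 75721328 to 75757818, plus strand) stood at 384 CPM in ITGB4-high cells and at 25.3 ± 0.896 CPM (SD, n = 2) in controls, a 15.19-fold rise (log2 fold change 3.92, SE 0.15, adjusted p = 0.0148, edgeR). S100A2, a calcium-binding protein of basal keratinocytes, rose with it, to 111 CPM against 1.13 in controls (6.59, adjusted p = 0.0148). Keratin KRT75 rose too, to 75.6 against 2.48 CPM (4.94, adjusted p = 0.0148). The basal keratin KRT5 did not pass (0.40, adjusted p = 0.638). The list of 13 keratins, which holds KRT5 but not KRT75, was not called (median 1.10, camera adjusted p = 0.208, 3 higher and 2 lower adjusted over the list alone). The Rap1 and Ras effector RASIP1 (5.80), the netrin and BMP-family receptor NEO1 (3.71) and the neuropeptide GAL (3.31) rose as well. The extracellular matrix and mesenchymal genes FBN1 (-3.65), a microfibril protein, and LOX (-3.57), which crosslinks collagen, fell, as did TGFB2 (-5.20, adjusted p = 0.0277), a TGF-beta ligand that stood at 3.5 CPM against 129 in controls, and the dynein gene DNAH11 (-5.89). GAL lies on chromosome 11. PLCH2, CCDC91 and EYA4, named after their values were seen, were higher too. In all, 14 genes passed, 9 higher and 5 lower.

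At an unadjusted p under 0.05, 3844 genes differed between ITGB4-high and control cells. Core mesenchymal genes did not pass the test: fibronectin FN1 was at 1943 against 9636 and 9699 CPM in control clones 1 and 3 (log2 fold change -2.31, adjusted p = 0.0524) and the repressor of epithelial genes ZEB1 at 113 against 311 and 278 CPM (-1.39, adjusted p = 0.0608). CDH2 was at -1.77 (adjusted p = 0.131), VIM at 0.04 (0.943), SNAI1 at 0.40 (0.604) and SNAI2 at 0.82 (0.378). Keratin KRT14 was at 1.46 CPM against 0.069 and 0.046, both under the floor of 3 counts, with an adjusted p = 0.0608. The ITGB4-high arm is 1 library, and the count moved with the others. RLE factors gave 74 genes (31 higher, 43 lower), the replicate block 363 (120 higher, 243 lower), DESeq2 1517 and limma-voom 2. Without control clone 1 or control clone 3, 0 genes passed in edgeR (1662 and 1405 at an unadjusted p under 0.05), and without LM2 clone 1 or LM2 clone 3, 6611 and 6422 passed.

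By gene list, mesenchymal markers had the smallest adjusted p between the cultured states: of 44 tested, 2 fell over all genes (FBN1 and LOX), 25 were lower and 5 higher adjusted over the list alone, and the median was -2.06 (camera adjusted p = 9.89e-05). This list's adjusted p = 0.902 with an estimated correlation. Cell cycle inhibitors and dormancy-associated genes were lower too (29 tested, median -0.92, adjusted p = 0.00258), with TGFB2 called over all genes and 9 lower and 1 higher adjusted over the list alone, as were type I interferon response genes (42 tested, median -0.72, adjusted p = 0.000889, 11 lower over the list alone, 0 over all genes) and cholesterol synthesis genes (24 tested, median -0.60, adjusted p = 0.00258, 7 lower over the list alone, 0 over all genes). Each of these 3 had an adjusted p = 0.902 with an estimated correlation. ITGB4-high cells were higher for MAPK pathway output genes (25 tested, median 0.92, adjusted p = 0.0052, 4 higher and 1 lower over the list alone), for hemidesmosome and laminin-332 genes (11 tested, median 1.00, adjusted p = 0.0295, ITGB4 called over all genes and 4 higher over the list alone) and for epithelial junction genes (24 tested, median 0.45, adjusted p = 0.0156, 1 higher over the list alone). These also had an adjusted p = 0.902 with an estimated correlation. Camera called 12 of 29 lists, 4 higher and 8 lower. The other 5 were the G1/S (median -0.43, adjusted p = 0.0156), G2/M (-0.35, 0.0269), fibroblast marker (-2.34, 0.0295) and fatty acid synthesis (-0.53, 0.0411) lists, which were lower, and the NF-kB and inflammatory cytokine list (0.89, 0.0295), which was higher. With an estimated correlation, adjusted p = 0.956 for the G1/S, G2/M and NF-kB lists and adjusted p = 0.902 for the fibroblast and fatty acid lists. Left-out libraries ended 4 of these calls: NF-kB without control clone 1 (adjusted p = 0.0692), G2/M without control clone 3 (0.115), fibroblast markers without LM2 clone 1 (0.0701) or LM2 clone 3 (0.0728), and fatty acid synthesis without control clone 3 (0.135), LM2 clone 1 (0.0544) or LM2 clone 3 (0.0551). Genes of the short arm of chromosome 17 had a median log2 ratio of -0.81 in ITGB4-high cells over control clone 1 (150 genes), and those of distal 3q a median of 0.39 (264 genes). Smaller shifts in both directions were seen over whole chromosomes, such as -0.213 on chromosome 2 (670 genes) and 0.174 on chromosome 19 (556 genes).

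The central comparison set all lung-recovered ITGB4-low cells (n = 3) against the cultured controls (n = 2), asking what differs in ITGB4-low cells after the inflamed lung. ITGB4 stood at 471 CPM in LM2 clone 1, 442 in LM2 clone 3 and 306 in the bleomycin library, beside 25.9 and 24.6 in the controls and 384 in ITGB4-high cells, a 16.07-fold rise over control (log2 fold change 4.01, SE 0.25, adjusted p = 0.0116). KRT75 (6.53, SE 0.32, adjusted p = 0.006), at 228 ± 54.9 CPM (SD, n = 3) against 2.48 ± 0.317 (SD, n = 2), and RASIP1 (6.40, adjusted p = 0.00598) rose as well. Also higher were the Notch ligand JAG2 (5.24, adjusted p = 0.0231), the serine protease inhibitor SERPINA1 (4.45, adjusted p = 0.0149) and its relative SERPINF1 (4.87, adjusted p = 0.0476), the podosome scaffold SH3PXD2A (4.68), the actin-binding protein ABLIM1 (4.26), the LIM protein CRIP2 (4.13), the interferon-induced gene XAF1 (4.22) and TCEAL9 (4.13). The genes that fell included GAS6, ligand of the AXL family of receptors, from 147 and 172 CPM in controls to between 20.5 and 25.3 in lung cells (log2 fold change -2.85, SE 0.15, adjusted p = 0.00678). They also included TGFB2 (-1.94, adjusted p = 0.0209), the connective tissue growth factor CCN2 (-3.04, adjusted p = 0.0461), the WNT inhibitor DKK1 (-2.20), the endocytic receptor LRP1 (-2.19), the myosin MYO1D (-2.88), the RNA-binding protein NANOS1 (-2.92), ARL15 (-1.87), TM4SF1 (-1.86) and VSTM2L (-1.83). GAS6 lies on chromosome 13, whose genes had a median log2 ratio of 0.30 in LM2 clone 1.

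Of 15673 genes, 78 passed in lung-recovered cells against control (42 higher, 36 lower), the smallest change being 2.107-fold, and 3220 did at an unadjusted p under 0.05. Core genes other than ITGB4 stayed above the threshold. ITGA6, the partner of ITGB4, was at 397 ± 111 CPM (SD, n = 3) against 159 ± 4.93 (SD, n = 2; log2 fold change 1.32, adjusted p = 0.0808), ZEB1 at 142 ± 20.01 against 295 ± 23.4 (-1.05, adjusted p = 0.0588) and the neural cadherin CDH2 at 115 ± 40.4 against 232 ± 21.7 (-1.02, adjusted p = 0.162). VIM (-0.32, adjusted p = 0.392) and MKI67 (0.10, adjusted p = 0.786) were close to control. Leaving out control clone 1 or control clone 3 left 0 genes in edgeR (1443 and 1005 at an unadjusted p under 0.05), leaving out the bleomycin library left 4, and leaving out LM2 clone 1 or LM2 clone 3 gave 393 and 1012. DESeq2 called 1278 genes and limma-voom 97, and with the clone as a replicate block 39 passed, 36 of them among the 78. SERPINF1 (adjusted p = 0.0632), TCEAL9 (0.0556), DKK1 (0.0683), LRP1 (0.0556), ARL15 (0.0533), TM4SF1 (0.0686) and VSTM2L (0.0512) did not pass with the block. Of the genes above, ITGB4, KRT75 and RASIP1 still passed without the bleomycin library. Without the ITGB4-high library SERPINF1, NANOS1, LRP1, TM4SF1 and VSTM2L reached an adjusted p = 0.0514 each, and CCN2 an adjusted p = 0.0768 without LM2 clone 1.

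**Figure D1:**
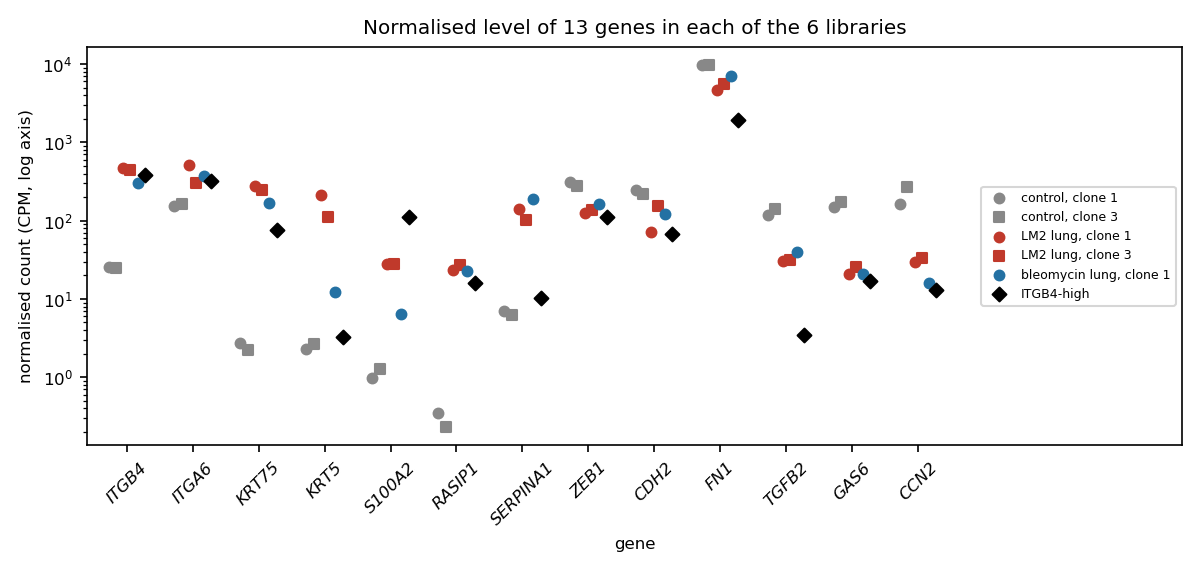
Normalised counts (CPM, log axis) of 13 genes in each of the 6 libraries, 1 point per library, with shape for the clone and colour for the group. ITGB4 lay between 306 and 471 CPM in the 3 lung libraries and at 384 in ITGB4-high cells, against 25.9 and 24.6 in the controls.

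Inflammatory genes were the list with the strongest shift in lung-recovered cells. Of 33 tested NF-kB and cytokine genes, 23 were higher in every lung library than in its own clone's control and the median log2 fold change was 2.73 (camera adjusted p = 3.42e-09; adjusted p = 0.734 with an estimated correlation). Over all genes 0 passed in edgeR, and 21 were higher adjusted over the list alone, for example the adhesion molecule ICAM1 (2.95), the chemokine CCL5 (5.09) and the cyclooxygenase PTGS2 (4.17), with IL6 at 3.82. The medians differed between libraries, at 3.45 in LM2 clone 1, 0.48 in LM2 clone 3 and 2.55 in the bleomycin library over their own controls. CXCL8 stood at 1058 CPM in LM2 clone 1 and 34.5 in LM2 clone 3, against 10.9 and 19.4 in controls, and it lies on chromosome 4, whose genes had a median log2 ratio of 0.38 in LM2 clone 1 (389 genes). Epithelial lists were higher as well. The junction list had 52 genes, of which only 24 were expressed enough to be tested. Of these, 11 were higher in every lung library than in its own clone's control and 1 was lower. Among 24 junction genes the desmosomal plaque protein DSP rose (1.61, adjusted p = 0.0231, or 0.0509 with the replicate block and 0.078 without the bleomycin library), 6 were higher adjusted over the list alone, and the median was 0.72 (camera adjusted p = 0.000482; adjusted p = 0.734 with an estimated correlation). Among 11 hemidesmosome and laminin-332 genes ITGB4 rose, and 6 were higher and 1 lower adjusted over the list alone (median 0.67, adjusted p = 0.00424; adjusted p = 0.734 with an estimated correlation). The higher ones included the laminin chain LAMB3 (5.30), and ITGB1 (-0.63) was the lower one.

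Of 13 keratins, KRT17 rose (adjusted p = 0.0491), from 0 and 0.092 CPM in controls, under the floor of 3 counts, to 16.1 and 18.6 CPM in LM2 clones 1 and 3 and 5.26 in the bleomycin library. It did not pass with the replicate block (adjusted p = 0.0556), nor without LM2 clone 1 (0.0649), the bleomycin library (0.0571) or the ITGB4-high library (0.0552). Adjusted over the list alone, 6 keratins were higher and 1, KRT4, was lower (median 2.45, adjusted p = 0.00632; adjusted p = 0.734 with an estimated correlation). The keratin call was lost without LM2 clone 1 (adjusted p = 0.0628), LM2 clone 3 (0.106) or the ITGB4-high library (0.103). KRT5, a basal keratin, was at 212 and 113 CPM in LM2 clones 1 and 3 and at 12.3 in the bleomycin library, against 2.29 and 2.67 in controls (log2 fold change 5.49, adjusted p = 0.118).

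Antigen presentation and interferon-gamma genes were higher in lung-recovered cells (27 tested, median 0.26, adjusted p = 0.0113; adjusted p = 0.734 with an estimated correlation), with CXCL10, on chromosome 4, called over all genes (adjusted p = 0.0355, or 0.0556 with the replicate block), at 3.07 to 4.42 CPM against 0.069 and 0.184 and 6 higher over the list alone. The lung metastasis signature, a list of genes raised in lung-seeking MDA-MB-231 derivatives, was higher (19 tested, median 1.18, adjusted p = 0.0143; adjusted p = 0.734 with an estimated correlation), with the BMP target ID1 called (2.73, adjusted p = 0.0274, or 0.0513 with the replicate block) and 10 higher and 2 lower over the list alone. MAPK output genes (25 tested, median 1.02, adjusted p = 0.00424; adjusted p = 0.734 with an estimated correlation; 0 members passed in edgeR over all genes or over the list alone), unfolded protein response genes (33 tested, median 0.38, adjusted p = 0.0025; adjusted p = 0.762 with an estimated correlation; 0 over all genes, 1 over the list alone) and p53 targets (29 tested, median 0.20, adjusted p = 0.0323; adjusted p = 0.734 with an estimated correlation; the stress cytokine GDF15 called at 2.81, 7 higher and 2 lower over the list alone) were higher too. G2/M genes completed the 10 lists called, all higher by camera (55 tested, median 0.26, adjusted p = 0.0227; adjusted p = 0.826 with an estimated correlation; 0 members passed). Libraries differed here. Over their own controls G2/M genes had medians of -0.26 in LM2 clone 1, 0.26 in LM2 clone 3 and 0.60 in the bleomycin library, with 10 of 55 higher in all 3. MAPK output genes were at 1.07, 0.013 and 1.16, unfolded protein response genes at 0.805, 0.303 and 0.0715, and antigen presentation genes at 0.017, 0.122 and 0.178. The G2/M call was lost without control clone 1 (adjusted p = 0.258), LM2 clone 3 (0.29) or the bleomycin library (0.381), the p53 call without control clone 1 (0.101), LM2 clone 1 (0.0607) or LM2 clone 3 (0.0946), and the lung metastasis call without control clone 1 (0.054). Without the bleomycin library CXCL10 (0.141), ID1 (0.111) and GDF15 (0.145) did not pass, and without either control 0 genes did.

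Mesenchymal markers were mixed in lung-recovered cells. Of 44 tested, CCN2 fell over all genes, and 15 were lower and 7 higher adjusted over the list alone. The median was -0.52 and the mean 0.02, with an adjusted p = 0.103 by camera and 0.0337 with the clone as a replicate block. Cell cycle inhibitors and dormancy-associated genes were not called (29 tested, median -0.03, adjusted p = 0.139), with GAS6 and TGFB2 lower over all genes and 2 higher and 7 lower over the list alone. Type I interferon genes (42 tested, median 0.16) had an adjusted p = 0.0564, or 0.0301 with the replicate block, with XAF1 and OAS2 (3.50, adjusted p = 0.0236, or 0.0778 without the bleomycin library) called over all genes and 9 higher and 4 lower over the list alone. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, moved from an adjusted p = 0.0722 to 0.0301 with the block (12 tested, median -0.40). Genes induced by tissue dissociation (42 tested, median 0.13, adjusted p = 0.172) and macrophage and myeloid markers (11 tested, median 0.65, adjusted p = 0.63) were not called. No list passed with an estimated correlation in this or any other comparison, the smallest adjusted p being 0.611, and fry called 0 lists on balance in one direction (smallest adjusted p = 0.0555).

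**Figure D2:**
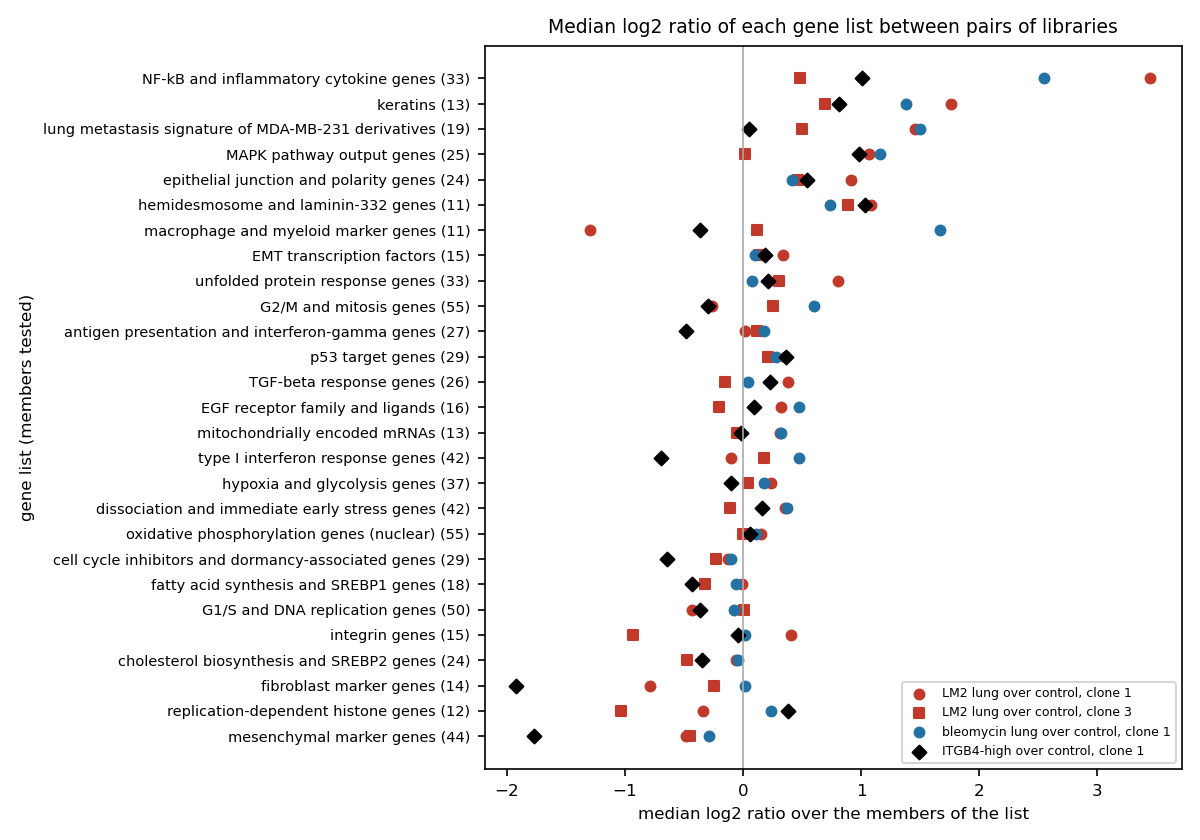
Median log2 ratio over the members of each gene list with at least 10 tested members, 1 point per pair of libraries (LM2 lung over control in clones 1 and 3, bleomycin lung over control in clone 1, ITGB4-high over control clone 1). NF-kB and inflammatory cytokine genes had medians of 3.45, 0.48, 2.55 and 1.01 in these pairs, and mesenchymal markers -0.48, -0.45, -0.29 and -1.77.

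Taken by trigger, the LM2 and bleomycin lung cells were each set against control. In LM2 lung cells (n = 2) 5 genes passed, all higher: KRT75 (log2 fold change 6.71, SE 0.19, adjusted p = 0.00999), RASIP1 (6.45, adjusted p = 0.0229), S100A2 (4.60, adjusted p = 0.0229), SERPINA1 (4.21, adjusted p = 0.0494) and ITGB4 (4.17, SE 0.14, adjusted p = 0.0122), which was at 456 ± 20.5 CPM (SD, n = 2). In the bleomycin library 4 passed, all higher: RASIP1 (6.30, adjusted p = 0.042), KRT75 (6.08, adjusted p = 0.0179), SERPINA1 (4.83, adjusted p = 0.0493) and ITGB4 (3.60, SE 0.15, adjusted p = 0.0323), a 12.1-fold rise. S100A2 was at 28 CPM in both LM2 libraries, 6.35 in the bleomycin library, 111 in ITGB4-high cells and 0.97 and 1.29 in controls. At an unadjusted p under 0.05, 2449 genes (1143 higher, 1306 lower) and 2266 genes (1043 higher, 1223 lower) differed, so the calls being all higher does not describe the wider set. The bleomycin arm is 1 library and was assumed to vary like the groups of 2. Left-out libraries moved both counts in edgeR. Without control clone 1 or control clone 3, 0 genes passed for LM2 (801 and 573 unadjusted) and 0 for bleomycin (815 and 692 unadjusted). Without LM2 clone 1, 1826 and 4424 passed, and without LM2 clone 3, 6303 and 4202. Without the ITGB4-high library 15 passed for LM2 and 3 for bleomycin, SERPINA1 reaching an adjusted p = 0.0527 for bleomycin. Without the bleomycin library SERPINA1 reached an adjusted p = 0.057 for LM2. The replicate block gave 36 and 8 genes, and limma-voom 2 and 3. DESeq2 called 647 for LM2 (352 higher, 295 lower) and 580 for bleomycin (254 higher, 326 lower).

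Inflammatory and epithelial lists were called for both triggers. NF-kB genes were higher in LM2 lung cells (median 2.97, adjusted p = 7.66e-07; adjusted p = 0.827 with an estimated correlation; 7 over the list alone) and in bleomycin lung cells (median 2.16, adjusted p = 2.88e-07; adjusted p = 0.873 with an estimated correlation; 1 over the list alone). Camera called 10 lists for LM2 and 9 for bleomycin. Epithelial junction genes (medians 0.71 for LM2 and 0.51 for bleomycin, adjusted p = 1.66e-05 and 0.0109), keratins (2.57 and 2.15, adjusted p = 7.88e-05 and 0.0461), hemidesmosome genes (0.67 and 0.66, adjusted p = 0.00412 and 0.0212) and antigen presentation genes (0.09 and 0.17, adjusted p = 0.0366 and 0.00416) were higher in both. For these lists adjusted p = 0.827 with an estimated correlation for LM2 and adjusted p = 0.873 for bleomycin. Adjusted over the list alone, 7 junction, 6 keratin, 5 hemidesmosome and 7 antigen presentation genes were higher for LM2, with 1 keratin and ITGB1 lower, and for bleomycin 1, 4, 1 and 4 were higher, with 2 keratins lower. MAPK output genes were higher in both (0.73 and 1.32, adjusted p = 0.0198 and 0.00346; with an estimated correlation, adjusted p = 0.833 and adjusted p = 0.873). LM2 lung cells were higher for unfolded protein response genes (median 0.49, adjusted p = 9.7e-06), p53 targets (0.32, adjusted p = 0.02) and the lung metastasis signature (1.46, adjusted p = 0.0366) and lower for histone genes (-0.77, adjusted p = 0.00875). These 4 had an adjusted p = 0.827 with an estimated correlation. They were not called for bleomycin, but its medians were close for the lung metastasis signature (1.49) and p53 targets (0.281). For unfolded protein response and histone genes the bleomycin medians were nearer to control, at 0.125 and -0.205. Bleomycin lung cells were higher for G2/M genes, of which 54 of 55 lay above control clone 1 (median 0.51, adjusted p = 1.83e-06), type I interferon genes (0.36, adjusted p = 0.00416, 6 over the list alone) and macrophage and myeloid markers (1.77, adjusted p = 0.00135). These 3 had an adjusted p = 0.873 with an estimated correlation.

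The bleomycin and LM2 list calls that depended on 1 library were these. For LM2, antigen presentation genes lost the call without control clone 1 (adjusted p = 0.063), without LM2 clone 3 (0.193) and with the replicate block (0.0679). MAPK output genes lost it without LM2 clone 1 (0.536), p53 targets without control clone 1 (0.0704) or LM2 clone 3 (0.0569), the lung metastasis signature without control clone 1 (0.0736), and histone genes without control clone 3 (0.0645) or LM2 clone 3 (0.206). For bleomycin, keratins lost it without control clone 1 (0.0716), LM2 clone 1 (0.299) or LM2 clone 3 (0.139). Of the macrophage and myeloid markers, the calprotectin genes S100A9 (3.31) and S100A8 (2.03), which epithelial cells can also express, were higher adjusted over the list alone. S100A9 was at 15.8 CPM in the bleomycin library against 1.66 and 1.52 in controls, while the macrophage genes CD68 and LYZ were at 1.60 and 0.449 CPM, and PTPRC, a marker of all white blood cells, at 2.69 CPM. Of the 11 macrophage and myeloid markers tested, 9 lay above control clone 1 in the bleomycin library and 2 below.

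Lung-recovered cells were then set against ITGB4-high cells, asking whether ITGB4-low cells from the lung became like the ITGB4-high state. ITGB4 itself did not differ detectably (log2 fold change 0.08, SE 0.26, adjusted p = 0.894). The interferon-induced gene XAF1 was higher in lung cells (log2 fold change 7.76, SE 0.73, adjusted p = 0.0409), at 47.8 to 90.3 CPM against 0.292, as were TGFB2 (3.26, adjusted p = 0.039), which stood at 33.7 ± 4.87 CPM (SD, n = 3) between 3.5 in ITGB4-high cells and 129 in controls, and the homeobox gene PKNOX2 (2.28, adjusted p = 0.0409). MYO1D (-4.10, adjusted p = 0.0368), NEO1 (-2.95, adjusted p = 0.0372), GAL (-2.18, adjusted p = 0.039), the RNA polymerase I subunit POLR1G (-1.77) and the ubiquitin ligase subunit FBXO45 (-1.55) were lower. XAF1 lies on the short arm of chromosome 17, where ITGB4-high cells had a median log2 ratio of -0.81, FBXO45 in distal 3q, where it was 0.39, and GAL and PKNOX2 on chromosome 11. The cornified envelope protein PPL was also lower in lung cells (adjusted p = 0.0426, or 0.102 with the replicate block), at 0.064 to 0.256 CPM, near or under the floor of 3 counts, against 10.5. In all, 17 genes passed (5 higher, 12 lower) and 2863 at an unadjusted p under 0.05 (1631 higher, 1232 lower). With the replicate block 0 passed in edgeR (2320 unadjusted), as without control clone 1 (1807), control clone 3 (1789) or the bleomycin library (2534). Without LM2 clone 1, 1432 passed (852 higher, 580 lower), and without LM2 clone 3, 37 (22 higher, 15 lower), with GAL and FBXO45 at adjusted p = 0.0562 and 0.0563. DESeq2 called 1086 (789 higher, 297 lower) and limma-voom 15 (2 higher, 13 lower), so the balance of higher and lower genes differed between fits.

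Interferon and mesenchymal lists were higher in lung-recovered cells than in ITGB4-high cells. Over control, ITGB4-high cells had medians of -0.716 for type I interferon genes, -2.06 for mesenchymal markers and -0.923 for dormancy-associated genes. Lung cells had 0.164, -0.52 and -0.0288 over control, with none of the 3 lists called in the main camera test. For these lists the gap therefore lay mostly in low levels of the 1 ITGB4-high library. Type I interferon genes (42 tested) had a median of 1.09, with XAF1 called and 16 higher and 1 lower over the list alone (adjusted p = 2.08e-10; adjusted p = 0.78 with an estimated correlation). Antigen presentation genes had a median of 0.91 with 10 higher over the list alone, among them HLA-B (0.99) and GBP5, at 3.90 to 8.46 CPM against 0.219, and 0 over all genes (adjusted p = 9.71e-07; adjusted p = 0.611 with an estimated correlation). Mesenchymal markers had a median of 1.35 with 13 higher and 2 lower over the list alone and 0 over all genes (adjusted p = 1.33e-06; adjusted p = 0.611 with an estimated correlation). The collagen COL6A1 was at 118, 210 and 256 CPM in lung cells against 4.96 in ITGB4-high cells. Dormancy-associated genes were higher (median 0.67, adjusted p = 0.00192; adjusted p = 0.611 with an estimated correlation), with TGFB2 called over all genes, and so were G2/M genes (median 0.64, adjusted p = 5.3e-06; adjusted p = 0.937 with an estimated correlation). Camera called 11 lists, the rest being cholesterol synthesis (0.25, adjusted p = 0.0181; adjusted p = 0.859 with an estimated correlation), fibroblast markers (1.85, adjusted p = 0.0184), histone genes (-0.67, adjusted p = 0.0214), the lung metastasis signature (1.31, adjusted p = 0.0246), NF-kB genes (1.35, adjusted p = 0.042) and G1/S genes (0.23, adjusted p = 0.0467). With an estimated correlation, adjusted p = 0.78 for the fibroblast, histone and lung metastasis lists and adjusted p = 0.937 for the NF-kB and G1/S lists. The NF-kB call was lost with the replicate block (0.087), without LM2 clone 1 (0.862) and without the bleomycin library (0.0824). Without LM2 clone 1 the cholesterol (0.0541), histone (0.118) and lung metastasis (0.24) calls were lost, without LM2 clone 3 the G1/S call (0.518), and without the bleomycin library the G1/S and fibroblast calls (0.0771 each).

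Bleomycin lung cells (n = 1) were compared with LM2 lung cells (n = 2) to ask whether the triggers left different profiles. No gene passed: 0 were called by edgeR, with 723 at an unadjusted p under 0.05, 56 by DESeq2 and 0 by limma-voom. The 723 are under a share of 0.05 of the 15673 genes tested, so they give no evidence of a difference between the triggers. Without LM2 clone 1, 1168 passed, and without LM2 clone 3, 2969. Macrophage and myeloid markers were higher in the bleomycin library (11 tested, median 1.82, adjusted p = 1.13e-08; adjusted p = 0.757 with an estimated correlation), with S100A9 (4.64) and S100A8 higher over the list alone. S100A8 was at 3.78 CPM in the bleomycin library and at 0.155, under the floor of 3 counts, and 0.32 CPM in LM2 clones 1 and 3. So were G2/M genes (median 0.45, adjusted p = 2.78e-08), type I interferon genes (0.21, adjusted p = 0.00528) and histone genes (0.97, adjusted p = 0.00528). Lower were unfolded protein response genes (-0.44, adjusted p = 1.57e-06) and keratins (-0.79, adjusted p = 0.00013; adjusted p = 0.757 with an estimated correlation), with KRT5 (-3.72), KRT14 (-2.64) and KRT7 (-1.48) lower over the list alone. For the G2/M, interferon, histone and unfolded protein lists adjusted p = 0.846 with an estimated correlation. The interferon and unfolded protein calls were lost without LM2 clone 1 (adjusted p = 0.765 and 0.0748) and the histone call without LM2 clone 3 (0.196). With the replicate block camera called 9 lists in place of 6, adding epithelial junction (adjusted p = 0.0185), fibroblast (0.0377) and G1/S genes (0.00993).

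Changes were last compared between pairs of libraries that shared no library, over 10746 genes that are not independent replicates. LM2 over control in clone 1 and in clone 3 correlated with Pearson's r of 0.599 (Spearman's coefficient 0.508), and bleomycin in clone 1 with LM2 in clone 3 at 0.662 (0.555). ITGB4-high over control clone 1 correlated with LM2 in clone 3 at 0.522 (0.449), ITGB4-high over control clone 3 with LM2 in clone 1 at 0.65 (0.557) and with bleomycin in clone 1 at 0.584 (0.453). Of 478 genes at least 2-fold higher in ITGB4-high cells than in control clone 1, 83.7% were also higher in LM2 clone 3 than in its control, against 47.1% of all genes. Of 987 genes at least 2-fold lower, 81.8% were also lower, against 52.9% of all genes. Median changes of these sets in LM2 clone 3 were 0.42 and -0.49, against 1.40 and -1.56 in ITGB4-high cells. Bleomycin and LM2 over the same clone 1 control correlated at 0.762, where simulations with no effect gave 0.501. The covariance was 0.457 against 0.115 simulated, a difference of 0.342. These simulations gave control and lung libraries the same spread for a gene. In the data the control pair was closer than the LM2 pair (biological coefficient of variation 0.078 against 0.31). The simulated values are therefore not a measured baseline for a shared control.

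**Figure D3:**
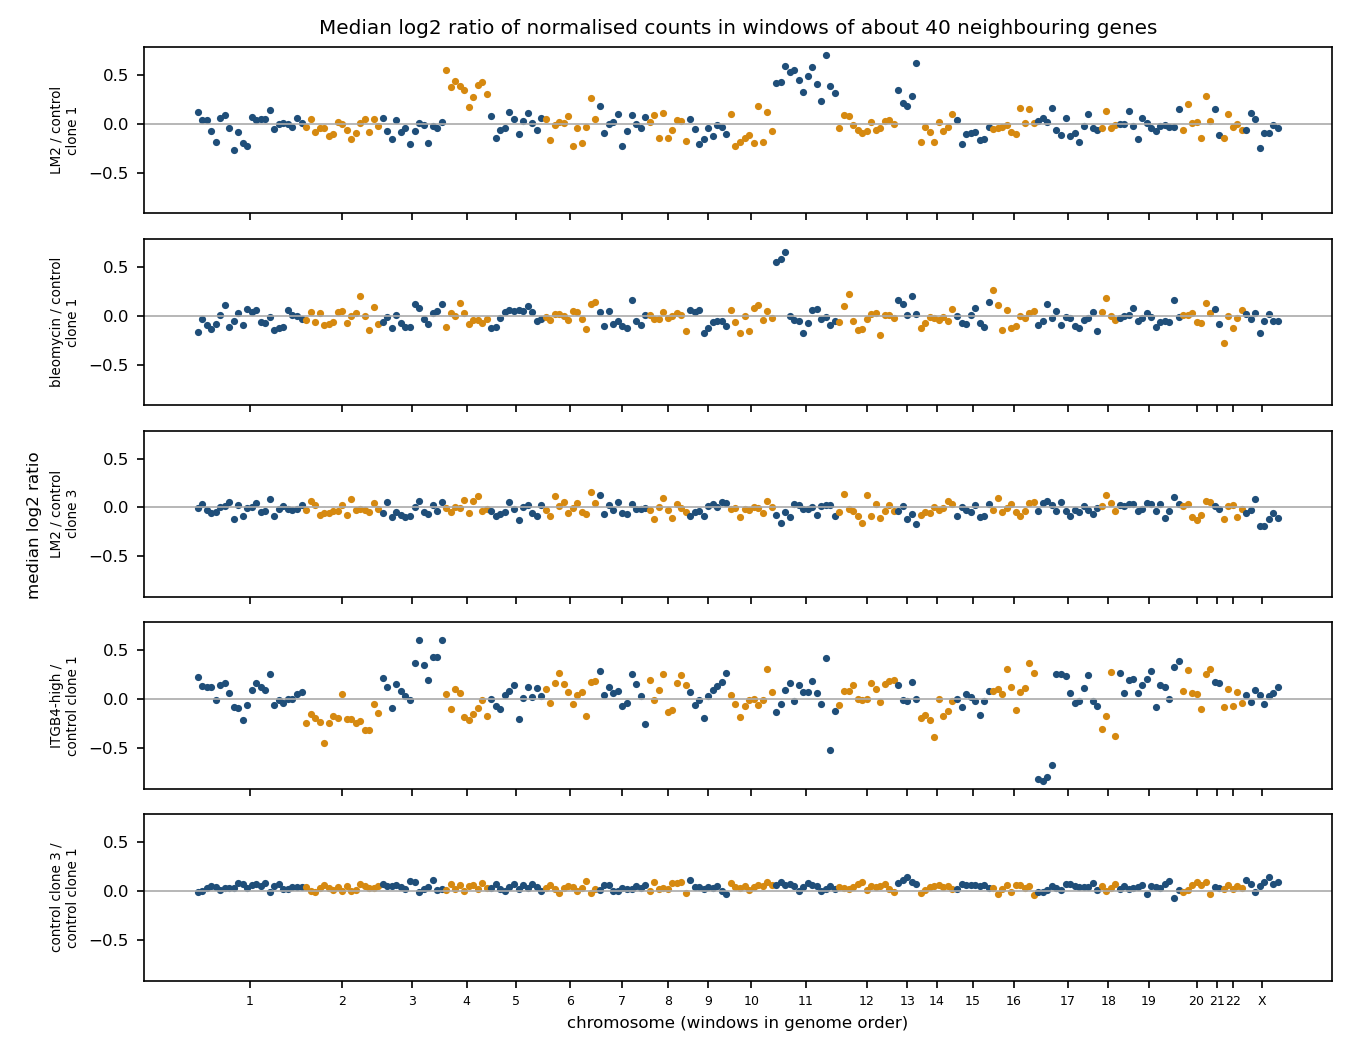
Median log2 ratio in windows of 40 neighbouring genes along the chromosomes, 1 panel per library ratio. LM2 clone 1 over its control had medians of 0.38, 0.47 and 0.30 on chromosomes 4, 11 and 13, and ITGB4-high cells a median of -0.81 on the short arm of chromosome 17.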

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

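Except for the correction for GC content, gene length and level, the tests in this part were chosen after the results they bear on had been seen. HBEGF, a ligand of the EGF receptor, moved in opposite directions in the LM2 clones among the 50 genes looked at: its log2 ratio to its own clone's control was 3.53 in clone 1 (68.6 against 5.82 CPM) and -0.65 in clone 3 (4.35 against 6.89 CPM), a difference of 4.18. The difference was not tested, since each clone gave 1 pair of libraries.

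ITGB4 in lung-recovered ITGB4-low cells reached the level of cultured ITGB4-high cells. A mixture with cells like the ITGB4-high library would need from 78.2% of such cells in the bleomycin library to 124% in LM2 clone 1. The short arm of chromosome 17, at a median log2 ratio of -0.806 in ITGB4-high cells, would then fall to -0.588 or lower, but its lowest median in a lung library was -0.003, which argues against outgrowth of cells like those sequenced, while ITGB4-high cells of another kind stay open. LM2 cells carried through the sort could not raise ITGB4 12.1-fold in the bleomycin library, which was given no LM2 cells, but in the LM2 libraries carry-over stays open, because no profile of LM2 cells was used: 2 genes were at 5 CPM or more in LM2 clone 1 and under 0.4 CPM outside the LM2 libraries, 0 were in LM2 clone 3, and the bleomycin library had 2 by a like count. Passage through the lung, overnight culture and sorting cannot be told apart from the trigger, as 0 libraries came from lungs without one.

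The LM2 pair differed more than the control pair, and this spread sets most of the counts. Without chromosomes 4, 11 and 13 its biological coefficient of variation was still 3.8 times that of the control pair, so the chromosome shifts do not account for it. Depth differed less within the LM2 pair (1.12-fold) than within the control pair (1.59-fold). Control-like cells diluting LM2 clone 3 would scale every gain alike only if undiluted clone 3 cells had the gains of clone 1, which was not measured. The gain in clone 3 was taken in percent of that in clone 1 over 167 genes at least 4-fold higher in LM2 clone 1. Its median was 14.3%, and it spanned 79.3 points from the 10th to the 90th percentile. Dilution therefore stays open. LM2 clone 1 stood further from the bleomycin library of its own clone (coefficient 0.267) than LM2 clone 3 did (0.213), but with 1 library of each a difference between clones or mice remains open, and other splits were not applicable, since no comparison had 3 in both groups.

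Genes of chromosomes 4, 11 and 13 shifted upward together in LM2 clone 1, with medians of 0.38, 0.47 and 0.30 over its control. Correction for GC content, length and level left at least 89.9% of each median, which argues against a bias from these. Each median also lay at percentile 100 of random gene sets. Those sets were drawn without regard to position, and the chromosomes were picked from the same scan. Clustering of co-regulated neighbours was therefore not tested. The lower quartile of the ratios moved by 58.6% or more of the upper quartile's move on each of these chromosomes, as a shift of most genes would give. Chromosome 13 was also at percentile 100 in control clone 3 (0.101) and in the bleomycin library (0.112) over control clone 1, so part of its 0.30 may lie in that shared control. A copy-number gain in the recovered cells may be the cause of the rest, but no DNA was analysed here.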

How the results depend on the processing

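The chromosome exclusion and the class-weighted limma-voom fit were chosen after the data were seen. In the order LM2, bleomycin, ITGB4-high and all lung cells against control, then lung cells against ITGB4-high, edgeR called 5, 4, 14, 78 and 17 genes, and 0 for bleomycin against LM2. Those called kept their direction under the alternatives that tested them, 13 of 17 being tested for lung cells against ITGB4-high under 1 CPM in 2 libraries. With no filter 1748, 1430, 2707, 2152, 1406 and 236 passed, and with DESeq2 647, 580, 1517, 1278, 1086 and 56. RLE factors gave 14 for LM2 and 74 for ITGB4-high, and no robust empirical Bayes 14 and 69. Limma-voom gave 2 for LM2 and 2 for ITGB4-high, and 1 CPM in 2 libraries gave 4, 2, 11, 55 and 0 (2651 for the last at an unadjusted p under 0.05 in edgeR). That filter ended the calls of SERPINA1 for LM2 (adjusted p = 0.0608) and bleomycin (0.0701), RASIP1 for bleomycin (0.0515), NEO1 for ITGB4-high (0.0502) and, for all lung cells against control, SERPINF1, LRP1 and VSTM2L (0.0545 each), NANOS1 and TM4SF1 (0.0564 each), CCN2 (0.051) and KRT17 (0.0573). The replicate block gave 36, 8, 363, 39 and 0. Without chromosomes 4, 11 and 13, 18, 19 and 161 passed for LM2, bleomycin and ITGB4-high. Class weights gave 662 for lung cells against control and 1023 against ITGB4-high. For these the cause was not tested. Leaving out each library gave 0 to 6303, 0 to 4424, 0 to 6611, 0 to 1012, 0 to 1432 and 0 to 2969. The highest counts came where an LM2 library was left out, so that the spread rested on the control pair (coefficient of variation 0.078) in place of the LM2 pair (0.31) in the fit with 4 groups.

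Of 1400 results for single genes under alternatives, 1091 kept direction and side of the threshold, 216 lost the call, 87 gained it and 6 turned sign, each at an adjusted p of 0.704 or more: VIM for ITGB4-high without control clone 1 (-0.021; range over left-out libraries to 0.090), and for all lung cells SNAI2 without LM2 clone 1 (-0.17, to 0.94), EGFR without control clone 3 (-0.030) and LM2 clone 1 (-0.20, to 0.35), and MKI67 without control clone 1 (-0.0025, to 0.23) and the bleomycin library (-0.0026). The cause was not tested. Of 484 results for lists, 327 kept the call and 157 lost it. Beyond the values printed with the results, the replicate block changed no other list call. Correlations moved to 0.635 for bleomycin in clone 1 with LM2 in clone 3 at a mean log2 CPM of 4 or more, and to 0.635 at 0 or more and 0.666 at 4 or more for ITGB4-high with LM2 in clone 1. Depth sets a floor of 0.135 to 0.22 CPM, so absence below that was not detectable.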

Other observations

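In this part the tests of genes restricted to ITGB4-high cells and of chromosomes were chosen after the results were seen, while the gene lists were planned. Of 15 genes at 10 CPM or more in ITGB4-high cells and under 0.4 CPM in both controls, most stayed far under the ITGB4-high level in lung-recovered cells. Their median was 2.21% of that level in LM2 clone 1, 4.65% in the bleomycin library and 3.92% in LM2 clone 3. The genes were picked for high values in the 1 ITGB4-high library, so lower values elsewhere follow in part from the choice. Some still rose over control. COL17A1, the hemidesmosomal collagen, was at 60.4 CPM in ITGB4-high cells, 9.92 in LM2 clone 1, 2.37 in LM2 clone 3 and 1.60 in the bleomycin library. In control clones 1 and 3 it was at 0.139 and 0.092 CPM, under the floor of 3 counts. ALDH1A1, a retinal dehydrogenase, was at 22.8 CPM in ITGB4-high cells and at 0.256 or less in the lung libraries. RASIP1 lay at 142% to 168% and CCDC91 at 73.5% to 127% of the ITGB4-high level, and HTATIP2 at 102% in the bleomycin library, 101% in LM2 clone 3 and 2% in LM2 clone 1.

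Integrin genes as a list were not called in lung-recovered cells over control (15 tested, median -0.21, camera adjusted p = 0.898), and members went both ways. Adjusted over the list alone, ITGB4 (4.01), ITGA2 (2.85), ITGA6 (1.32) and ITGA3 (0.67) were higher and ITGA11 (-2.24), ITGA1 (-1.80) and ITGB1 (-0.63) lower. Ligands and cytokines of chromosome 4 exceeded that chromosome's median shift of 0.38 in LM2 clone 1 by far, with log2 ratios of 6.59 for CXCL8, 5.17 for AREG and 4.43 for EREG, against 0.83, 1.64 and 1.25 in LM2 clone 3. In the bleomycin library, the part of chromosome 11 before 28 Mb had a median of 0.592 (119 genes) and the rest of the chromosome -0.036 (436 genes). LM2 clone 3 had medians of -0.079 and -0.005 there.

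The other lists were not called in lung-recovered cells over control. Their medians were -0.252 for cholesterol synthesis, -0.0704 for fatty acid synthesis and -0.166 for G1/S genes (adjusted p = 0.0611, 0.14 and 0.14), 0.162 for hypoxia and glycolysis, 0.08 for oxidative phosphorylation, 0.169 for mitochondrially encoded mRNAs (adjusted p = 0.14, 0.164 and 0.14), 0.522 for EMT transcription factors (0.355), 0.173 for the EGF receptor family (0.693) and 0.185 for TGF-beta response genes (0.82). Markers of other cell types had medians of -0.274 for fibroblasts (0.2), 0.492 for endothelium (0.693) and -0.161 for lung epithelium (0.898). Over the list alone, 2 fibroblast markers were higher and 5 lower. Reads were aligned to hg38, so these medians do not measure mouse RNA left from the lung. Whether mouse reads aligned to human genes was not tested.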
